A study of Canis lupus familiaris with 89 samples.

How the data were processed

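Polyadenylated RNA of 89 mammary gland samples from 16 dogs was sequenced on an Illumina HiSeq2000, per the labels and the series design text. The reads were aligned with HISAT2 to the dog genome build CanFam3.1 and checked with FastQC, per the submitters' processing notes, which give no versions. The deposited files hold read counts per gene, in a separate file for each library, with 32496 gene rows, 26678 of them with at least 1 read. The program that counted the reads, the annotation release and the strand setting are not given in the sources used here, so that reads of overlapping or antisense genes cannot be told apart. The authors also deposited a series-wide table of scores per gene symbol, in which every gene has a mean of 0 and an SD of 1 over the libraries. How these deposited scores were made is not stated, and differences within a dog follow log2 CPM of the counts while differences between dogs are smaller than in the counts.

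The count tables name genes by Ensembl identifier. Symbols were taken from the table of scores, whose columns were paired with gene rows by their values, and a pair was used where the profile within dogs fitted 1 gene row (lowest correlation of a pair 0.99954, median 0.999951, highest correlation with the next best row 0.9727). Of 11503 symbols, 9340 were used in this way and 2163 columns were not used. A further 197 merged gene rows held 3.95% of the gene reads. The reference table of gene symbols belongs to another assembly, UU_Cfam_GSD_1.0, and served for names only, so that no positions are reported.

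Rows that name no gene were left out of library sizes and tests. As a mean over libraries, 37.4% of reads were not aligned, 16.0% overlapped no gene and 0.078% were ambiguous. Gene reads averaged 36.2 ± 13.2 M per library (SD, n = 89). No libraries had identical counts (0 pairs), and the highest correlation between 2 libraries was 0.9723. Libraries of 1 dog came from the same animal per the labels, and their profiles were checked to resemble each other more than those of different dogs, by a difference in correlation of 0.102 within classes. Most library preparations held 1 dog, and the difference was 0.144 over pairs of the same preparation and 0.102 over pairs of different sequencing runs.

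The class and the detailed histology were taken from the labels, which call the middle class benign, while the series design text calls it pre-malignant. Tests used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total count 15), estimateDisp, glmQLFit with robust estimation and glmQLFTest, and with dog as a fixed block. Classes were compared in 1 fit of all libraries, and the detailed histology types in a second such fit. Tumor diameter was tested as a log2 slope with class and dog in the model. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given for scale only, since a share of about 0.05 of unchanged genes falls under that limit. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM with TMM-scaled library sizes.

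Gene lists, 26 in all with 479 entries of which 388 were tested under a symbol, were fixed before the count files were opened. Each was tested in every comparison with camera (limma 3.58.1, preset inter-gene correlation 0.01), with adjustment over all 234 tests, beside camera with an estimated correlation and fry. List scores are means of centred log2 CPM over the members tested under a symbol, which were 6 of 16 for skeletal muscle and 9 of 18 for adipocyte. Named genes followed a rule fixed in advance. In the class comparisons these were the 10 largest increases and the 10 largest decreases among called genes with a symbol, an average log2 CPM of at least 1 and the same sign in at least 12 of 16 dogs. For the histology types and diameter the 6 largest each way were taken. To these came genes fixed in advance, among them ESR1, PGR, ERBB2, PRLR, MKI67 and KRT5, and up to 4 members of each list. Some genes that fell under this rule are not reported here. Further list members were named as examples after their values were seen: MYBL2, COL2A1, GPD1, PPARG, CFD in benign tumors, GHR, LCK and HSPA5.

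Alternatives were no dog block, dog as a random effect (limma-voom), counts summed per dog and class or subtype, sequencing run added, RNA integrity number or adipocyte score as a covariate, RLE size factors, no filter on low counts, DESeq2 1.42.0, a test against a 1.5-fold change, omission of atypias and carcinomas in situ, omission of complex adenomas and mixed carcinomas, tumor diameter as a covariate, and omission of each dog or of single libraries. Omission of the 14 libraries with a skeletal muscle score above 3, and of single libraries of mixed carcinoma, carcinoma in situ and atypia from the list tests, was added after the data had been seen. So were fits without the covariate of the 81 libraries with an RNA integrity number and of the 59 tumors with a diameter, and comparisons of pairs within library preparations and across sequencing runs. The RNA integrity number was missing for 8 libraries and the diameter for 4 tumors. Class differences in RNA integrity and tissue scores were tested by permuting classes within dogs with 100000 resamples.

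The steps were tested on simulated counts with 200 planted genes per comparison. Genes planted at 2-fold were recovered in 90% of cases for malignant against normal, 91% for malignant against benign, 83% for complex adenoma against adenoma, 16% for mixed carcinoma against carcinoma, 20% for carcinoma in situ against carcinoma, 42% for atypia against lobular hyperplasia and 41% for lobular hyperplasia against duct ectasia. At 4-fold these shares were 95%, 98%, 98%, 62%, 76%, 79% and 90% in the same order. Of the unchanged genes in each comparison, 4 to 10 were called. Counts were drawn for each gene on its own with the fitted dispersions, and planted genes had an average log2 CPM of at least 1. Correlation between genes was thus left out, so that these shares do not measure false calls in the data. With shuffled types the data gave up to 682 called genes for atypia against lobular hyperplasia. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.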

Results

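Polyadenylated RNA was sequenced from 89 mammary gland samples taken from 16 dogs, and read counts per gene were compared between tissue classes within dogs. The class labels held 26 normal, 41 benign and 22 malignant libraries, and each of the 16 dogs contributed to all classes. By detailed histology the normal class consisted of 14 lobular hyperplasias, 6 duct ectasias, 4 atypias and 2 samples called normal. Of the atypias, normal replicate 15 is called normal in the simplified histology of the labels. Most of its libraries thus came from non-neoplastic lesions rather than unaltered gland. The benign class held 23 adenomas and 18 complex adenomas, which are tumors with a luminal and a myoepithelial component. The malignant class held 15 carcinomas, 4 mixed carcinomas, in which cartilage or bone can occur, and 3 carcinomas in situ. Reads assigned to genes ranged from 6.09 to 68.4 M per library. They averaged 34.6 ± 13.5 M in normal (SD, n = 26), 35.2 ± 13.6 M in benign (SD, n = 41) and 40 ± 12.1 M in malignant libraries (SD, n = 22).

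RNA quality and adipocyte content differed between normal libraries and both tumor classes. The RNA integrity number, a score of RNA intactness with a maximum of 10, averaged 7.94 ± 1.5 in normal libraries (SD, n = 22). It averaged 9.22 ± 0.602 in benign (SD, n = 40) and 9.16 ± 0.961 in malignant libraries (SD, n = 19). With classes permuted within dogs (absolute differences, 9 tests in the family), it was higher by 1.22 in malignant than in normal libraries (adjusted p = 0.0023). It was higher by 1.28 in benign than in normal libraries (adjusted p = 0.00012). The adipocyte score, the mean of centred log2 CPM over the list, fell by 1.01 from normal to malignant libraries (adjusted p = 0.00012). It fell by 1.02 from normal to benign libraries (adjusted p = 0.00012). The skeletal muscle score fell by 1.76 from normal to benign libraries (adjusted p = 0.025), and differed by -1.52 between malignant and normal libraries (adjusted p = 0.1). Malignant and benign libraries differed by -0.0621 in RNA integrity (adjusted p = 0.93), 0.237 in the muscle score (0.9) and 0.0042 in the adipocyte score (0.99). Single libraries had high muscle scores, with 8 normal, 3 benign and 3 malignant libraries above 3. CKM, the creatine kinase of muscle, averaged 996 ± 2250 CPM in normal (SD, n = 26), 210 ± 1210 CPM in benign (SD, n = 41) and 28.3 ± 88.4 CPM in malignant libraries (SD, n = 22).

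**Figure D1:**
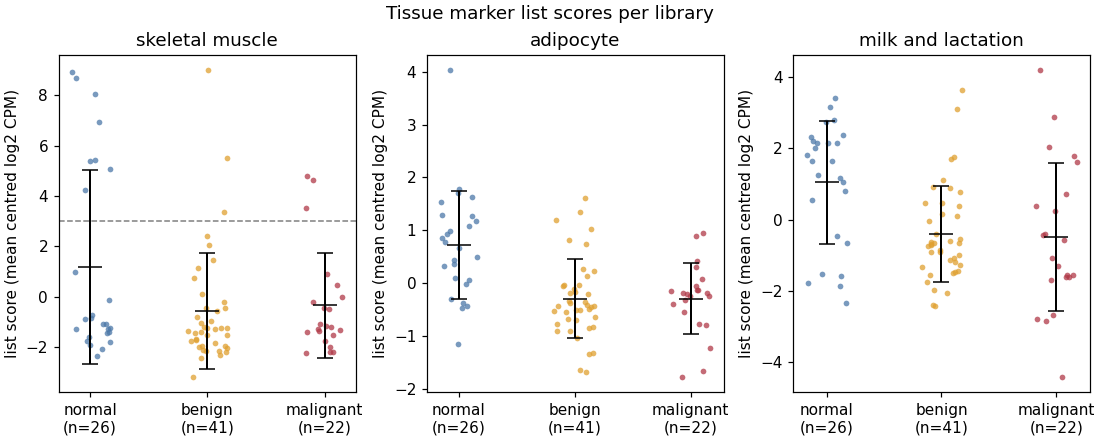
Scores of the skeletal muscle, adipocyte and milk lists per library (points; mean of centred log2 CPM over list members) in normal (n = 26), benign (n = 41) and malignant (n = 22) libraries, with the mean and SD as bars and a muscle score of 3 as a dashed line. The adipocyte score averaged 0.72 in normal, -0.3 in benign and -0.29 in malignant libraries.

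The first comparison asked which genes separated malignant from normal tissue of the same dogs. COL11A1 (ENSCAFG00000019985), a fibrillar collagen chain, rose by 3.53 ± 0.56 on the log2 scale (SE; adjusted p = 0.000111; higher in 15 of 16 dogs). It averaged 44.3 ± 104 CPM in normal (SD, n = 26) and 377 ± 495 CPM in malignant libraries (SD, n = 22). COL11A2 rose by 2.64 ± 0.55, HAPLN1, which links hyaluronan to proteoglycans, by 2.9 ± 0.83, and EDIL3, a secreted integrin ligand, by 2.81 ± 0.52. FABP4, the fatty acid carrier of adipocytes, fell by 2.76 ± 0.64 (adjusted p = 0.00765; lower in 15 of 16 dogs), and the mucin MUC4 fell by 2.36 ± 0.6. MKI67, a marker of dividing cells, rose by 1.61 ± 0.39 (adjusted p = 0.00969; higher in 13 of 16 dogs). PGR, the progesterone receptor gene, fell by 1.2 ± 0.39 (adjusted p = 0.0452). It was called in 5 of 16 omissions of 1 dog (highest adjusted p = 0.0995, without dog 47). ESR1, the estrogen receptor alpha gene, differed by -0.98 ± 0.4 and did not pass the threshold (adjusted p = 0.109).

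Other large increases in malignant against normal libraries were those of SLC35F1 (2.78), EPHA7 (2.4), OLFM2 (2.36), ANOS1 (2.22), NDUFA4L2 (2.14) and the metalloprotease ADAMTS17 (2.03), as log2 changes. The decreases included GPC3, a cell surface proteoglycan (-2.58), ITIH3 (-2.49), C1QTNF12 (-2.42; lower in 16 of 16 dogs) and CLEC3B (-2.38). SPP2 (-2.37), the lipoxygenase ALOX15 (-2.27), HSPB7 (-2.22) and GALNT15 (-2.03) fell as well. PRLR, the prolactin receptor gene, differed by -1.04 ± 0.38 (adjusted p = 0.0746), ERBB2 by -0.28 ± 0.11 (adjusted p = 0.119) and the basal keratin KRT5 by -0.13 ± 0.31 (adjusted p = 0.837).

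Of 30 measured proliferation genes, 7 rose and 0 fell, among them TOP2A (1.29 ± 0.36) and MYBL2 (1.04 ± 0.3), and 9 rose when adjusted over the list alone. The proliferation list moved up (camera adjusted p = 4.87e-09), with adjusted p = 0.596 with an estimated correlation. The proliferation score rose with RNA integrity within dogs (r = 0.499, n = 81; adjusted p = 0.00034) and among normal libraries (r = 0.493, n = 22; adjusted p = 0.037). In the hypoxia and glycolysis list 10 of 17 genes rose, including CA9, a carbonic anhydrase induced by low oxygen (1.91 ± 0.48), and the hexokinase HK2 (1.23 ± 0.32). Adjusted over the list alone, 10 rose and 1 fell. The hypoxia list moved up (adjusted p = 0.000941), with adjusted p = 0.596 with an estimated correlation. Among 16 cartilage and bone matrix genes 4 rose, COL2A1 (2.35 ± 0.6) beside COL11A1, COL11A2 and HAPLN1, and 5 rose when adjusted over the list alone. This list had an adjusted p = 0.00132, and adjusted p = 0.373 with an estimated correlation. Of 25 interstitial matrix genes 3 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. FN1, the fibronectin gene, rose by 1.41 ± 0.43 and COL12A1 by 1.41 ± 0.29, and DCN, the decorin gene, fell by 1.3 ± 0.39. The interstitial matrix list moved up (adjusted p = 0.006), with adjusted p = 0.765 with an estimated correlation. It was not called with RNA integrity as a covariate (adjusted p = 0.0977, against 0.0416 in the same 81 libraries without it). Of 16 cholesterol synthesis genes 2 rose, with HMGCS1 at 0.69 ± 0.16, and 5 rose when adjusted over the list alone. Cholesterol synthesis moved up as a list (adjusted p = 0.00289), with adjusted p = 0.596 with an estimated correlation.

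Adipocyte genes fell in 5 of 9 cases, among them GPD1 (-1.18 ± 0.3) and PPARG (-0.96 ± 0.27), and in 7 when adjusted over the list alone. The adipocyte list moved down in malignant against normal libraries (adjusted p = 1.2e-05), with adjusted p = 0.25 with an estimated correlation. The adipocyte score was lower where RNA integrity was higher within dogs (r = -0.581, n = 81; adjusted p = 7.5e-05). The list was not called with its own score as a covariate (adjusted p = 0.901). Milk genes fell in 2 of 12 cases, BTN1A1 (-1.55 ± 0.48) and ELF5 (-1.22 ± 0.37), and in 8 when adjusted over the list alone. The milk list had an adjusted p = 3.7e-05, and adjusted p = 0.373 with an estimated correlation. ELF5 and GATA3 (-0.8 ± 0.25) were the 2 of 18 luminal epithelium genes that fell, against 4 when adjusted over the list alone. The luminal list had an adjusted p = 0.000259, and adjusted p = 0.582 with an estimated correlation. In the hormone response list PGR and the chemokine gene CXCL12 (-1.07 ± 0.3) fell among 15 genes, and 5 fell when adjusted over the list alone. This list moved down (adjusted p = 0.00267), with adjusted p = 0.498 with an estimated correlation. EGFL7 (-1.14 ± 0.32) was the 1 of 12 endothelial genes to fall, with 2 when adjusted over the list alone. The endothelial list had an adjusted p = 0.0112, and adjusted p = 0.765 with an estimated correlation. With the adipocyte score as a covariate it turned upward (adjusted p = 0.019) and EGFL7 turned to 0.1, and with RNA integrity it was not called (adjusted p = 0.188, against 0.00599 in the same 81 libraries without it). JUN (-0.7 ± 0.22) was the 1 of 16 immediate early genes to fall, with 2 when adjusted over the list alone. That list had an adjusted p = 0.0465, and adjusted p = 0.802 with an estimated correlation. It was not called with the adipocyte score as a covariate (adjusted p = 0.101) or without the libraries of high muscle score (adjusted p = 0.0536).

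In all, 1227 of 16806 genes changed between malignant and normal libraries, 743 upward and 484 downward (edgeR quasi-likelihood test with dog as a block, adjusted p under 0.05). The count was 20 with the adipocyte score as a covariate and 0 without the 14 libraries of high muscle score (1789 at an unadjusted p under 0.05). In the 81 libraries with a known RNA integrity it was 1518, and 103 with RNA integrity as a covariate. Over the called genes the median absolute log2 change went from 0.8 (median SE 0.22) to 0.42 (0.23) with the score and 0.62 (0.25) without the 14 libraries, and in the 81 libraries from 0.87 (0.24) to 0.69 (0.25). The number of called genes was 4 against a 1.5-fold change, 2151 with DESeq2, 759 without atypias and carcinomas in situ, 288 without dog 13 and 624 without dog 89.

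Benign tumors were compared with normal tissue in the same fit. LRP2, the gene of the endocytic receptor megalin, showed the largest named increase, by 3.43 ± 0.7 on the log2 scale (SE; adjusted p = 0.00105; higher in 15 of 16 dogs). HAPLN1 (3.06 ± 0.84), EDIL3 (2.73 ± 0.49; higher in 16 of 16 dogs) and COL11A1 (2.52 ± 0.54) rose as well. Milk protein genes fell, CSN3 (kappa casein) by 4.21 ± 0.99, CSN1S1 (alpha casein) by 3.92 ± 1.06, LALBA (alpha-lactalbumin) by 3 ± 0.69 and CSN2 (beta casein) by 2.53 ± 0.82. CSN3 averaged 715 ± 975 CPM in normal (SD, n = 26) and 284 ± 983 CPM in benign libraries (SD, n = 41). The muscle genes CKM (-5.3 ± 1.48; adjusted p = 0.0125; lower in 13 of 16 dogs) and DES, the desmin gene (-3.38 ± 0.79), fell beside them. CKM turned to 0.23 with the adipocyte score as a covariate. FABP4 (-2.91 ± 0.51) and MUC4 (-2.54 ± 0.49) fell too.

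Further increases in benign against normal libraries were SLC5A8 (2.43), CSPG5 (2.4), OLFM2 (2.35), SCRG1 (2.2), IL1RL1, a receptor for interleukin 33 (1.97), and ENPP3 (1.93). HSPB7 (-2.53) and TMOD4, a tropomodulin of muscle (-2.31), fell. Hormone receptor genes did not pass the threshold, with ESR1 at 0.41 ± 0.34 (adjusted p = 0.455), PGR at 0.38 ± 0.33 (adjusted p = 0.472) and PRLR at 0.47 ± 0.34 (adjusted p = 0.379). MKI67 differed by 0.84 ± 0.34 (adjusted p = 0.0831), ERBB2 by -0.07 ± 0.1 (adjusted p = 0.698) and KRT5 by 0 ± 0.28 (adjusted p = 0.997).

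Milk genes fell in 7 of 12 cases in benign against normal libraries, and 1 rose and 7 fell when adjusted over the list alone. The milk list moved down (adjusted p = 4.26e-05), with adjusted p = 0.395 with an estimated correlation. Adipocyte genes fell in 7 of 9 cases, for instance RBP4 (-1.4 ± 0.41) and CFD (-1.32 ± 0.34), and in 7 when adjusted over the list alone. Their list had an adjusted p = 3.7e-05, and adjusted p = 0.267 with an estimated correlation. Of 12 endothelial genes 6 fell, for instance TIE1 (-0.88 ± 0.24), and FLT1 rose (0.77 ± 0.22), with 8 down and 1 up when adjusted over the list alone. The endothelial list moved down (adjusted p = 0.000291), with adjusted p = 0.596 with an estimated correlation. The T and NK cell genes GZMK (-1.15 ± 0.32), CCL5 (-1.18 ± 0.31) and LCK (-0.66 ± 0.2) were the 3 of 12 that fell, against 6 when adjusted over the list alone. That list had an adjusted p = 0.000114, and adjusted p = 0.592 with an estimated correlation. CKM and MYBPC2 (-1.01 ± 0.34) fell among the 6 of 16 skeletal muscle list members tested under a symbol, and 3 fell when adjusted over the list alone. The skeletal muscle list had an adjusted p = 0.0423, and adjusted p = 0.743 with an estimated correlation. ATF3 (-0.79 ± 0.18) fell among 16 immediate early genes, and 3 fell when adjusted over the list alone. Immediate early genes had an adjusted p = 0.0478 as a list, and adjusted p = 0.802 with an estimated correlation. They turned upward with the adipocyte score as a covariate (adjusted p = 0.0361). In that fit the adipocyte (adjusted p = 0.984), endothelial (0.318) and skeletal muscle lists (0.858) were not called. For the adipocyte list this follows from construction, since the score is the mean of its own members. Without the libraries of high muscle score the skeletal muscle (adjusted p = 0.901) and immediate early lists (0.0911) were not called.

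Cartilage and bone matrix genes rose in 6 of 16 cases in benign tumors, with ACAN, the aggrecan gene of cartilage, at 2.85 ± 0.78, and 6 rose and 1 fell when adjusted over the list alone. The cartilage list had an adjusted p = 0.0404, and adjusted p = 0.596 with an estimated correlation. TPX2 (0.88 ± 0.24) was the 1 of 30 proliferation genes to rise, with 1 also when adjusted over the list alone. The proliferation list had an adjusted p = 0.00267, and adjusted p = 0.802 with an estimated correlation. In the unfolded protein response list HSPA5, SEL1L and DNAJC3 (0.6 ± 0.15) rose and ATF4 (-0.44 ± 0.13) fell among 16 genes. Adjusted over the list alone, 6 rose and 1 fell. The list moved up (adjusted p = 0.0269), with adjusted p = 0.692 with an estimated correlation. Of 16 cholesterol synthesis genes 2 rose, with DHCR7 at 0.66 ± 0.17, and 2 rose also when adjusted over the list alone. Cholesterol synthesis had an adjusted p = 0.00494 as a list, and adjusted p = 0.596 with an estimated correlation. Of 43 PAM50 genes, which sort human breast tumors, 3 rose, for instance EXO1 (0.84 ± 0.27), and 0 when adjusted over the list alone. The PAM50 list moved up (adjusted p = 0.0248), with adjusted p = 0.677 with an estimated correlation. With the adipocyte score as a covariate the cartilage (adjusted p = 0.199), proliferation (0.564) and PAM50 lists (0.279) were not called. With RNA integrity as a covariate the proliferation (adjusted p = 0.189) and PAM50 lists (0.584) were not called, against 0.0146 and 0.0425 in the same 81 libraries without it. The unfolded protein response list was not called in those 81 libraries (adjusted p = 0.0757) or without the libraries of high muscle score (0.281).

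Benign and normal libraries differed in 2002 of 16806 genes, 1084 upward and 918 downward in the same test. The count was 0 with the adipocyte score as a covariate (1582 at an unadjusted p under 0.05) and 2 without the libraries of high muscle score. In the 81 libraries with a known RNA integrity it was 2588, and 27 with RNA integrity as a covariate. Over the called genes the median absolute log2 change went from 0.66 (median SE 0.18) to 0.26 (0.19) and 0.53 (0.21) in the fits of score and muscle, and in the 81 libraries from 0.73 (0.19) to 0.49 (0.21). Called genes numbered 788 with sequencing run added to the block, 39 against a 1.5-fold change (9 upward, 30 downward), 987 without complex adenomas and mixed carcinomas, 977 without dog 13, 1260 without dog 83 and 3117 without dog 47.

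**Figure D2:**
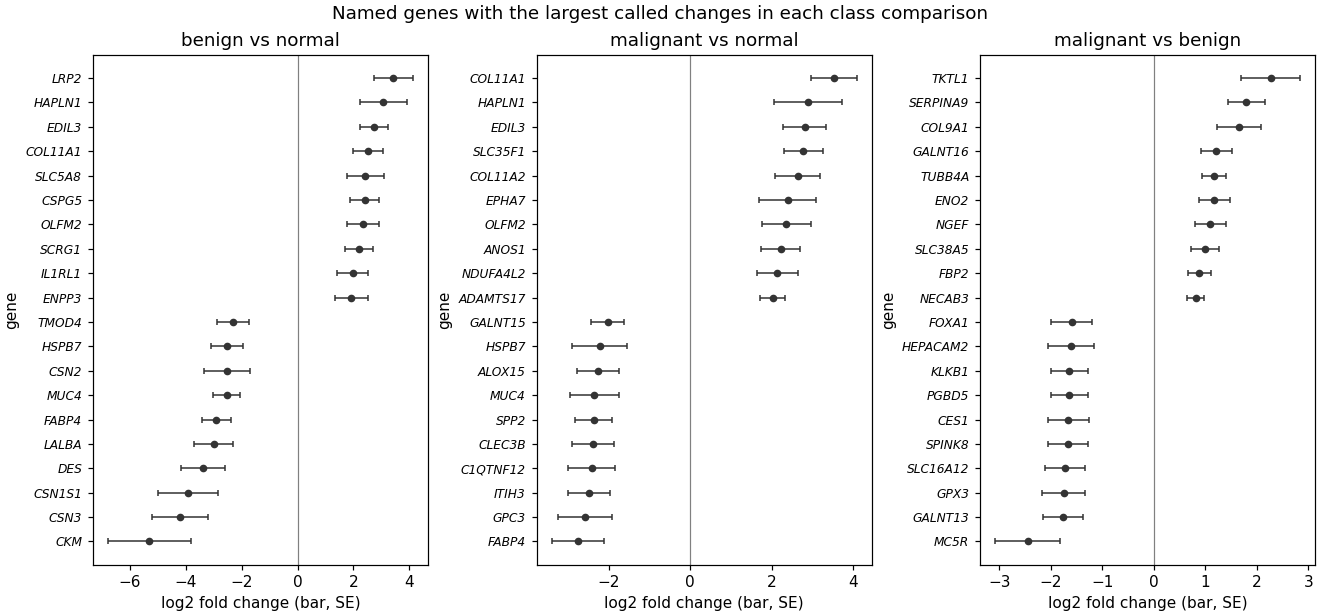
Log2 fold changes (points, with the SE as bars) of the genes with the largest named changes in benign against normal, malignant against normal and malignant against benign libraries, from the edgeR model with dog as a block (26 normal, 41 benign and 22 malignant libraries). COL11A1 lies at 3.53 in malignant against normal and 2.52 in benign against normal libraries, and CKM at -5.3 in benign against normal libraries.

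Both comparisons used the same normal libraries, so that their changes were correlated partly by construction. Across genes, which are not independent replicates, the log2 changes of benign and of malignant against normal correlated with r = 0.739. With the classes shuffled within dogs 99 times, r averaged 0.55 (0.178 to 0.755). The covariance was 0.228, against a mean of 0.0618 (0.0174 to 0.142) in the shuffles. In both comparisons 366 genes rose and 258 fell, and 0 genes went in opposite directions. Independent lists of these sizes would share 47.9 and 26.4 genes, which leaves out the shared normal libraries, so that part of the excess may come from them. Benign changes from 8 dogs were also set against malignant changes from the other 8, so that no library was shared. Over 20 such splits r averaged 0.373 ± 0.11 (SD; 0.116 to 0.557). Shuffled classes gave a mean of -0.0023 (-0.417 to 0.427), and 1 of 80 shuffles reached the observed mean. Normal libraries differed from both tumor classes in RNA integrity and adipocyte score, which splitting the dogs does not remove. Changes common to the tumors can thus not be told apart from these differences by the split.

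Malignant tumors were compared with benign tumors to find genes that separated the tumor classes. Hormone receptor genes fell in malignant libraries, PGR by 1.58 ± 0.38 on the log2 scale (SE; adjusted p = 0.0225; lower in 13 of 16 dogs) and PRLR by 1.51 ± 0.37 (adjusted p = 0.0296; lower in 12 of 16 dogs). ESR1 fell by 1.39 ± 0.38 (adjusted p = 0.0491; lower in 11 of 16 dogs) and GHR, the growth hormone receptor gene, by 0.92 ± 0.23. PGR averaged 6.97 ± 9.45 CPM in malignant (SD, n = 22), 18.7 ± 13.6 CPM in benign (SD, n = 41) and 18.7 ± 20.9 CPM in normal libraries (SD, n = 26). The luminal transcription factor genes FOXA1 (-1.6 ± 0.4) and GATA3 (-0.91 ± 0.24) fell with them. FOXA1 averaged 29.1 ± 36.7 CPM in malignant (SD, n = 22) and 87.7 ± 77.9 CPM in benign libraries (SD, n = 41). TKTL1, a transketolase-like gene, rose by 2.27 ± 0.57, the serpin SERPINA9 by 1.79 ± 0.36 (adjusted p = 0.00922; higher in 15 of 16 dogs) and the cartilage collagen gene COL9A1 by 1.65 ± 0.42.

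**Figure D3:**
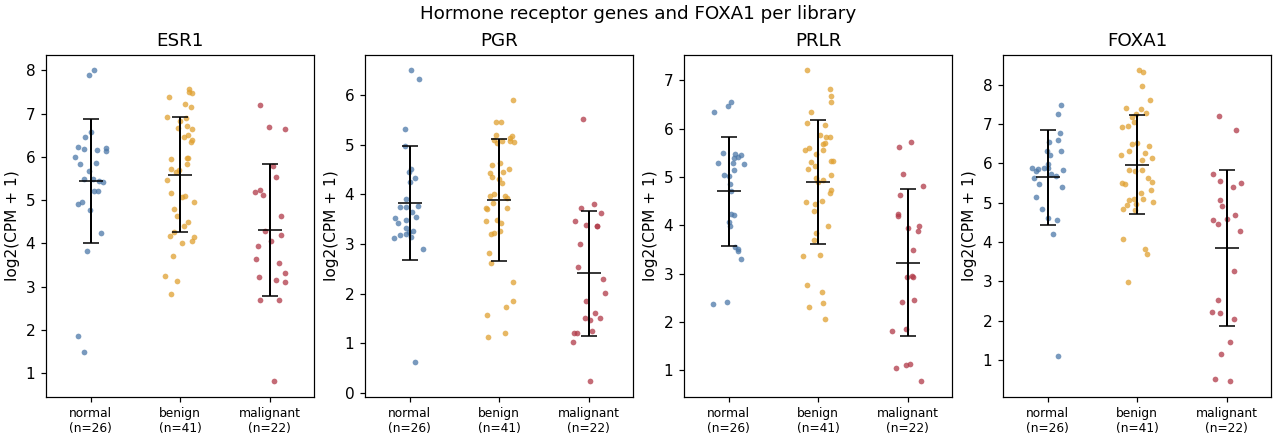
Expression of ESR1, PGR, PRLR and FOXA1 per library (points; log2 of CPM + 1) in normal (n = 26), benign (n = 41) and malignant (n = 22) libraries, with the mean and SD as bars. Malignant libraries lie lower than benign libraries on average in all panels, by -1.39 for ESR1, -1.58 for PGR, -1.51 for PRLR and -1.6 for FOXA1 as fitted log2 changes, and their ranges overlap.

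Other increases in malignant against benign tumors were GALNT16 (1.21), the neuronal enolase ENO2 (1.17), the tubulin TUBB4A (1.17), NGEF (1.09), SLC38A5 (0.99), FBP2 (0.88) and NECAB3 (0.81). The melanocortin receptor gene MC5R (-2.45), GALNT13 (-1.76), the secreted glutathione peroxidase GPX3 (-1.75), SLC16A12 (-1.72) and SPINK8 (-1.67) fell. The carboxylesterase CES1 (-1.66), PGBD5 (-1.64), KLKB1 (-1.64) and HEPACAM2 (-1.61) fell too. MKI67 differed by 0.77 ± 0.36 (adjusted p = 0.338), ERBB2 by -0.21 ± 0.11 (adjusted p = 0.383) and KRT5 by -0.13 ± 0.29 (adjusted p = 0.903), none past the threshold.

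In the hormone response list 4 of 15 genes fell in malignant against benign libraries, and 7 when adjusted over the list alone. It moved down (adjusted p = 1.35e-05), with adjusted p = 0.25 with an estimated correlation. Of 18 luminal epithelium genes, FOXA1 and GATA3 fell, and 1 rose and 3 fell when adjusted over the list alone. Luminal genes had an adjusted p = 0.0212 as a list, and adjusted p = 0.756 with an estimated correlation. ME1, the malic enzyme gene (-0.86 ± 0.2), fell among 16 fatty acid synthesis genes, and 2 rose and 5 fell when adjusted over the list alone. The fatty acid list moved down (adjusted p = 0.0216), with adjusted p = 0.565 with an estimated correlation. The proliferation list moved up (adjusted p = 0.000224; adjusted p = 0.765 with an estimated correlation) with 0 of 30 genes past the threshold, also when adjusted over the list alone. Of these genes 29 had a positive log2 change, with a median of 0.26. The interstitial matrix (adjusted p = 0.00398), hypoxia and glycolysis (adjusted p = 0.0223) and T and NK cell lists (adjusted p = 0.046) moved up with 0 genes past the threshold, also when adjusted over the list alone. These had adjusted p = 0.765, 0.765 and 0.802 with an estimated correlation. The hypoxia list was not called with RNA integrity as a covariate (adjusted p = 0.0549, against 0.0289 in the same 81 libraries without it) or without the dog block (0.158). Without the libraries of high muscle score the hypoxia (adjusted p = 0.0826) and luminal lists (0.103) were not called.

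Between malignant and benign libraries 153 of 16806 genes changed, 45 upward and 108 downward. The count was 0 with counts summed per dog and class (1925 at an unadjusted p under 0.05), with sequencing run added (1422), against a 1.5-fold change (398) and without complex adenomas and mixed carcinomas (1353). It was 2 in the 59 tumors of known diameter, with diameter as a covariate and also without it, 15 without the libraries of high muscle score, 27 without atypias and carcinomas in situ, 554 with DESeq2, 304 with dog as a random effect and 362 (227 upward, 135 downward) without the dog block, where the balance of directions turned. Over the called genes the median absolute log2 change went from 1.03 (median SE 0.25) to 0.96 (0.28) without the libraries of high muscle score, 0.88 (0.27) with sequencing run and 0.92 (0.31) without complex adenomas and mixed carcinomas. Leaving out 1 dog called 47 genes (dog 1), 23 (dog 13), 39 (dog 29), 90 (dog 36), 94 (dog 47), 2 (dog 54, both upward), 293 (dog 70) or 33 (dog 82). Without dog 54 the adjusted p was 0.202 for PGR, 0.216 for PRLR, 0.304 for ESR1 and 0.216 for FOXA1. Over the omissions of 1 dog the log2 change came closest to 0 at -1.38 for PGR, -1.25 for PRLR, -1.17 for ESR1 and -1.37 for FOXA1.

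Within the benign class, complex adenomas were set against adenomas, and 8 dogs held both. Complex adenomas had more ACAN (3.24 ± 0.7; SE, log2; adjusted p = 0.0414), averaging 455 ± 802 CPM (SD, n = 18) against 62.8 ± 133 CPM in adenomas (SD, n = 23). EHD3, an endosomal trafficking gene, rose by 2.16 ± 0.4 (adjusted p = 0.0161), FMOD, the gene of the matrix proteoglycan fibromodulin, by 2.1 ± 0.44 and SPARCL1 by 1.78 ± 0.38. SV2A rose by 0.98 ± 0.19 and NPR2, the receptor gene of C-type natriuretic peptide, by 0.89 ± 0.19. SLC39A8, a metal ion transporter gene, fell by 1.95 ± 0.4 (adjusted p = 0.0414). It averaged 52.3 ± 58.6 CPM in complex adenomas (SD, n = 18) and 138 ± 117 CPM in adenomas (SD, n = 23). ESR1 (0.68 ± 0.47; adjusted p = 0.756), PGR (0.63 ± 0.44; adjusted p = 0.756) and MKI67 (-0.52 ± 0.44; adjusted p = 0.824) did not pass the threshold.

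**Figure D4:**
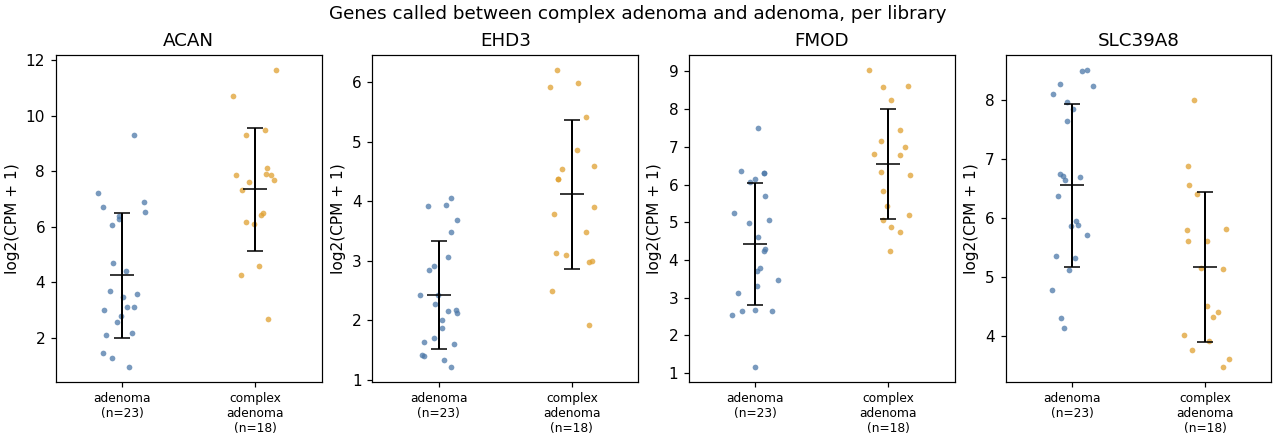
Expression of ACAN, EHD3, FMOD and SLC39A8 per library (points; log2 of CPM + 1) in adenomas (n = 23) and complex adenomas (n = 18), with the mean and SD as bars. The fitted log2 changes were 3.24 for ACAN, 2.16 for EHD3, 2.1 for FMOD and -1.95 for SLC39A8, and the points of both subtypes overlap in every panel.

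Of 16 cartilage and bone matrix genes, ACAN alone passed the threshold in complex adenomas, and 6 rose and 1 fell when adjusted over the list alone. The cartilage list moved up (adjusted p = 0.000305), with adjusted p = 0.25 with an estimated correlation. Contractile genes of smooth muscle and myoepithelium had 10 of 11 positive log2 changes and 0 past the threshold, also when adjusted over the list alone. The contractile list moved up (adjusted p = 0.000538), with adjusted p = 0.565 with an estimated correlation. Of 12 epithelial-mesenchymal transition factors 0 passed and 3 rose when adjusted over the list alone, with the vimentin gene VIM at 1.13 ± 0.26 (adjusted p = 0.0555). Their list moved up (adjusted p = 6.55e-05), with adjusted p = 0.25 with an estimated correlation. The proliferation (adjusted p = 0.00126), luminal epithelium (0.00493) and acute inflammation lists (0.00844) moved down, with adjusted p = 0.801, 0.652 and 0.652 with an estimated correlation. Hypoxia and glycolysis (0.000947), unfolded protein response (0.00329) and cholesterol synthesis (0.00393) moved down, with adjusted p = 0.596, 0.582 and 0.596 with an estimated correlation. These 6 lists had 0 genes past the threshold, also when adjusted over the list alone. Without the dog block the proliferation (adjusted p = 0.0937), acute inflammation (0.162), hypoxia (0.072) and cholesterol lists (0.0641) were not called.

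Complex adenomas and adenomas differed in 10 of 20243 genes, 8 upward and 2 downward, of which 7 carried a symbol. The count was 0 with counts summed per dog and subtype (897 at an unadjusted p under 0.05), with sequencing run added (1312), against a 1.5-fold change (630), without the libraries of high muscle score (1445) and with benign samples only (1633). It was 2 without a filter on low counts, 19 in the 81 libraries of known RNA integrity and 20 with that as a covariate, 22 with the adipocyte score as a covariate, 51 with dog as a random effect, 176 without the dog block (77 upward, 99 downward) and 200 with DESeq2. Leaving out 1 dog gave 0 (dogs 34, 69 and 82), 1 (dogs 17 and 89), 2 (dog 70), 3 (dogs 1 and 36), 4 (dog 54), 5 (dog 13), 16 (dog 83), 26 (dog 29) or 43 (dog 18). Each of the 7 named genes lost its call without at least 1 dog.

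Within the malignant class, carcinomas in situ were set against carcinomas. IL17RE and IL17RC, which encode receptor chains for interleukin 17 family cytokines, were higher in carcinomas in situ, by 1.76 ± 0.34 (SE, log2) and 1.22 ± 0.23 (adjusted p = 0.0272 each). IL17RE averaged 69.6 ± 49.1 CPM in carcinomas in situ (SD, n = 3) and 19.8 ± 4.54 CPM in carcinomas (SD, n = 15). IL17RC averaged 329 ± 178 CPM (SD, n = 3) and 145 ± 30.5 CPM (SD, n = 15). Of 15 interferon response genes 0 passed over all genes and 13 were lower when adjusted over the list alone, for example OAS2 (-1.81 ± 0.47; adjusted p = 0.342). The interferon list was lower in carcinomas in situ (adjusted p = 3.44e-15), with adjusted p = 0.25 with an estimated correlation. Of 13 macrophage genes 0 passed over all genes and 8 were lower when adjusted over the list alone, for example C1QC (-1.96 ± 0.61; adjusted p = 0.641). The macrophage list was lower (adjusted p = 7.98e-14), with adjusted p = 0.25 with an estimated correlation. The T and NK cell list was lower (adjusted p = 6.17e-07; adjusted p = 0.429 with an estimated correlation), with 0 of 12 genes past the threshold, also when adjusted over the list alone. Of 13 lists called in all, other cell type markers were the interstitial matrix (adjusted p = 0.000778), B and plasma cell (0.00338) and acute inflammation lists (0.0171), which were lower, with adjusted p = 0.708, 0.596 and 0.692 with an estimated correlation. The nerve and Schwann cell (adjusted p = 0.042) and contractile lists (0.0478) were higher, with adjusted p = 0.582 and 0.756 with an estimated correlation. These 5 lists had 0 genes past the threshold, also when adjusted over the list alone. Without malignant replicate 3 the B and plasma cell (adjusted p = 0.42), acute inflammation (0.91), nerve (0.889) and contractile lists (0.198) were not called. Without malignant replicate 12 the interstitial matrix (adjusted p = 0.287), B and plasma cell (0.0557) and nerve lists (0.158) were not called, nor the contractile list without malignant replicate 20 (0.26). The nerve and contractile lists were also not called without the dog block (adjusted p = 0.0567 and 0.174) or with the adipocyte score as a covariate (0.0727 and 0.148).

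IL17RE and IL17RC were the 2 genes of 20243 past the threshold with edgeR (1187 at an unadjusted p under 0.05), and 1 dog held both subtypes. The count was 0 with summed counts, with sequencing run added, against a 1.5-fold change, without the libraries of high muscle score or without malignant replicate 3. Without malignant replicate 12 it was 1, a gene other than these, and neither IL17RE nor IL17RC was called. It was 12 without malignant replicate 20, 14 without the dog block, 4 with dog as a random effect, 17 in the 81 libraries of known RNA integrity (6 higher, 11 lower), 10 with that as a covariate (4 higher, 6 lower) and 237 with DESeq2 (20 higher, 217 lower).

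Mixed carcinomas were compared with carcinomas through the other libraries of each dog, since 0 dogs held both. Of 11 contractile genes 0 passed over all genes and 5 were lower when adjusted over the list alone, for example the intermediate filament gene SYNM (-1.96 ± 0.64; adjusted p = 0.856). The contractile list was lower in mixed carcinomas (adjusted p = 9.07e-08), with adjusted p = 0.25 with an estimated correlation. The macrophage (adjusted p = 0.00203), T and NK cell (0.00181) and endothelial lists (0.00138) were lower, with adjusted p = 0.677, 0.652 and 0.652 with an estimated correlation. These lists had 0 genes past the threshold, also when adjusted over the list alone. Malignant replicate 5 had the lowest scores of the 4 mixed carcinomas in these lists, at -1.14, -2.28 and -1.23. Without it the adjusted p was 0.0402, 0.491 and 0.00562 in the same order. Of 9 lists called in all, the B and plasma cell (adjusted p = 0.0163), hormone response (0.0271) and basal adhesion lists (0.041) were lower too. None was called with an estimated correlation. Without malignant replicate 5 the B and plasma cell (adjusted p = 0.595) and hormone lists (0.0775) were not called. Without malignant replicate 2 the hormone (adjusted p = 0.114) and basal lists (0.522) were not called. Markers of tissue content were lower in this indirect fit as well. The adipocyte list (adjusted p = 0.00703) had 9 of 9 and the skeletal muscle list (0.0366) 6 of 6 negative log2 changes. The muscle scores themselves, -1.07, -1.3, 4.62 and -1.4, lay within the range of carcinomas (-2.23 to 4.8). Some other libraries of dogs 17 and 18 had high muscle scores (8.99, 8.91 and 8.03), so that the fitted fall does not show less muscle in mixed carcinomas. Both lists rest on this fit. The adipocyte and skeletal muscle lists had adjusted p = 0.582 and 0.692 with an estimated correlation and 0 genes past the threshold, also when adjusted over the list alone. The skeletal muscle list was not called without malignant replicate 4 (adjusted p = 0.212) or without malignant replicate 5 (0.104). With the adipocyte score as a covariate the macrophage (adjusted p = 0.119), T and NK cell (0.0645), endothelial (0.705), adipocyte (0.767) and skeletal muscle lists (0.516) were not called. For the adipocyte list this follows from construction, since the score is made from it. Without the dog block the macrophage (adjusted p = 0.339), T and NK cell (0.0714), adipocyte (0.207) and skeletal muscle lists (0.522) were not called. The T and NK cell list was not called in the 81 libraries of known RNA integrity (adjusted p = 0.581), nor were the adipocyte (0.0618) and skeletal muscle lists (0.855) without the libraries of high muscle score. The cartilage and bone matrix list was not called (adjusted p = 0.204), with CNMD at 3.13 ± 1.5 (adjusted p = 0.949). Without malignant replicate 2 this list was called as higher (adjusted p = 0.0264). With edgeR 0 of 20243 genes passed the threshold (1062 at an unadjusted p under 0.05, near the share of 0.05 that unchanged genes give). DESeq2 called 92, the fit without the dog block 13, the fit with dog as a random effect 4, and edgeR without malignant replicate 4 called 2.

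Types of lesion within the normal class gave no single gene past the threshold. Atypias (n = 4) had a lower adipocyte list than lobular hyperplasias (n = 14; adjusted p = 0.000203; adjusted p = 0.373 with an estimated correlation), with GPD1 at -1.54 ± 0.66 (adjusted p = 1). Immediate early genes were lower as a list (adjusted p = 4.87e-05; adjusted p = 0.582 with an estimated correlation), with DUSP1 at -1.27 ± 0.54 (adjusted p = 1). This list was not called without normal replicate 9 (adjusted p = 0.365). Cartilage and bone matrix genes were higher as a list (adjusted p = 0.00576; adjusted p = 0.498 with an estimated correlation). All 3 lists had 0 genes past the threshold, also when adjusted over the list alone. The T and NK cell list was called as higher too (adjusted p = 0.046), but not with an estimated correlation. It was not called without normal replicate 9 (adjusted p = 0.0597) and pointed downward without normal replicate 6 (0.0681). With the adipocyte score as a covariate the adipocyte (adjusted p = 0.463), immediate early (0.106) and cartilage lists (0.075) were not called. For the adipocyte list this follows from construction, since the score is made from it. The T and NK cell list was the 1 list kept. The cartilage list was also not called without the dog block (adjusted p = 0.474) or without the libraries of high muscle score (0.0686). Lobular hyperplasias had a lower macrophage list than duct ectasias (n = 6; adjusted p = 2.02e-05; adjusted p = 0.582 with an estimated correlation). Of its 13 genes 0 passed over all genes and 2 were lower when adjusted over the list alone, with CD68 at -1.92 ± 0.53 (adjusted p = 0.502). It was not called without the libraries of high muscle score (adjusted p = 0.677). The T and NK cell (adjusted p = 0.0124) and immediate early lists (0.00203) were lower beside it, with adjusted p = 0.765 and 0.677 with an estimated correlation and 0 genes past the threshold, also when adjusted over the list alone. In the 81 libraries of known RNA integrity these 2 lists were not called (adjusted p = 0.279 and 0.154), nor the T and NK cell list without the libraries of high muscle score (0.731). Their milk list was higher (adjusted p = 0.0257; adjusted p = 0.692 with an estimated correlation), with 0 of 12 past the threshold, also when adjusted over the list alone. The milk list was not called with RNA integrity as a covariate (adjusted p = 0.0549, against 0.00351 in the same 81 libraries without it), with the adipocyte score as a covariate (0.06) or without the libraries of high muscle score (0.197). With edgeR 0 genes passed and 616 of atypia against lobular hyperplasia and 1353 of lobular hyperplasia against duct ectasia had an unadjusted p under 0.05. Unchanged genes alone would give a share of about 0.05 of the 20243 tested, and the count for atypia lies below it. DESeq2 called 108 and 122, and the fit without the dog block 49 and 62. The fit with dog as a random effect called 1 gene between atypia and lobular hyperplasia.

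Tumor diameter, for which the labels give no unit, was known for 59 tumors and was tested on a log2 scale with class and dog in the model. Each value is thus a log2 change per doubling of diameter. All 25 interstitial matrix genes had positive slopes, with a median of 0.28, and the versican gene VCAN was at 0.55 ± 0.14 (adjusted p = 0.257). Of them 0 passed over all genes and 13 rose when adjusted over the list alone. The interstitial matrix list rose with diameter (adjusted p = 3.44e-15), with adjusted p = 0.25 with an estimated correlation. All 30 proliferation genes had negative slopes, with CDC20 at -0.35 ± 0.1 (adjusted p = 0.347), and 0 passed over all genes and 2 fell when adjusted over the list alone. The proliferation list fell with diameter (adjusted p = 4.8e-14), with adjusted p = 0.565 with an estimated correlation. Of 12 milk genes 0 passed over all genes and 5 fell when adjusted over the list alone, with BTN1A1 at -0.77 ± 0.18 (adjusted p = 0.199). The milk list fell with diameter (adjusted p = 0.00032), with adjusted p = 0.582 with an estimated correlation, and was not called without the dog block (adjusted p = 0.0979). Cell type markers moved beside these lists, and some of the 16 lists called in all are not named here. The luminal (adjusted p = 3.93e-05) and T and NK cell lists (0.0044) fell with diameter, with adjusted p = 0.582 and 0.708 with an estimated correlation. The macrophage (adjusted p = 5.15e-05), endothelial (0.0189) and contractile lists (0.0271) rose, with adjusted p = 0.582, 0.766 and 0.692 with an estimated correlation. These 5 lists had 0 genes past the threshold, also when adjusted over the list alone. The T and NK cell (adjusted p = 0.898) and contractile lists (0.793) were not called without the dog block, nor the T and NK cell (0.067) and endothelial lists (0.0911) without the libraries of high muscle score. With the adipocyte score as a covariate the contractile list was not called (adjusted p = 0.0547). With edgeR 0 of 16276 genes passed the threshold (1370 at an unadjusted p under 0.05). DESeq2 called 49, the fit without the dog block 12, and leaving out dog 34 gave 1.

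Libraries of the same class resembled each other more when they came from the same dog. Over the 2000 most variable genes the correlation of log2 CPM averaged 0.713 ± 0.0906 over 65 pairs from the same dog (SD) and 0.612 ± 0.0903 over 1311 pairs from different dogs. The difference was 0.102 (permutation of dogs within classes, p = 1e-05, the smallest that 100000 resamples can give). The means were 0.675 and 0.6 in normal, 0.725 and 0.629 in benign, and 0.705 and 0.569 in malignant pairs. Dogs and library preparations largely coincided, since of 13 preparations 5 held more than 1 dog. Among pairs of the same preparation the correlation averaged 0.721 ± 0.0856 over 61 pairs from the same dog (SD) and 0.577 ± 0.106 over 20 pairs from different dogs. That difference was 0.144 (permutation of dogs within class and preparation, p = 0.006). Among pairs of different sequencing runs the averages were 0.713 ± 0.0775 over 32 pairs from the same dog (SD) and 0.612 ± 0.0902 over 1309 pairs from different dogs. The difference was again 0.102 (permutation of dogs within classes, p = 1e-05). Of these pairs, 30 from the same dog but only 18 from different dogs shared the preparation, so that this difference does not separate dog from preparation. Pairs that shared it averaged 0.715 ± 0.0799 for the same dog and 0.558 ± 0.0931 for different dogs (SD).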

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

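Chosen only after the result was seen were the test on luminal genes, the muscle score limit of 3, the ratios within the 81 libraries of known RNA integrity and the number of groupings of the histology types, which was lowered from 40 for run time; the tests of muscle, RNA integrity and adipocyte ratios were set down after counts of called genes had been seen to drop but before any ratio was computed, and the wording for the other groupings of samples was revised after those had run, with the rule unchanged. Of 40 outlier tests, on 3 groups with several measures each, 4 stood out, where chance flags about 1 in 20 groups for each measure. Among duct ectasias, normal replicate 5 lay far below the others in PGR, at -0.76 log2 CPM against 3.1 to 4.16. Among mixed carcinomas, malignant replicate 4 lay far above the others in ESR1, at 5.77 log2 CPM against 2.93 to 3.17, and in the skeletal muscle score, at 4.62 against -1.4 to -1.07. Malignant replicate 5 lay far below the other mixed carcinomas in the macrophage score, at -1.14 against 0.33 to 0.57.

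The first pattern weighed was the difference of malignant from normal libraries, whose 1227 called genes fell to 0 without the muscle libraries, to 103 with RNA integrity (1518 in the same 81 libraries without it) and to 20 with the adipocyte score as a covariate. Muscle as the whole cause was argued against by the fold sizes, since the median ratio of the log2 change without the muscle libraries to that with them was 0.798 (quartiles 0.713 to 0.88), and the calls ended as the median absolute change went from 0.8 to 0.62 while its median SE went from 0.22 to 0.25. With RNA integrity as a covariate the ratio was 0.868 (quartiles 0.754 to 1). Against the same 81 libraries without the covariate it was 0.798 (quartiles 0.691 to 0.918). RNA integrity was itself higher by 1.22 in malignant than in normal libraries. Its part cannot be told apart from class, so that these ratios do not decide on it as a cause. With the trended dispersion of all libraries held, which also gave 0 without the muscle libraries, random removal of as many libraries per class left a median of 278.5 genes called and as few as 0 in 1 of 60 draws, so that fewer libraries lowered the count as well but seldom to 0. The adipocyte content of normal libraries cannot be told apart from class (0.612, quartiles 0.357 to 0.852), because the adipocyte score itself differed between the classes, and the class itself stays open as an untested explanation.

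The second pattern was the lower level of hormone response genes in malignant than in benign libraries, whose 4 called genes had a median ratio of the log2 change of 0.695 (lowest 0.627) without complex adenomas and mixed carcinomas and of 0.81 with sequencing run, fits in which 0 genes were called. Fewer luminal cells cannot be told apart from it. The median log2 change was -0.2 over all 18 luminal genes and -0.65 over all 15 hormone response genes. That gap was smaller than the SD of the luminal genes (0.68), the bound set for this test. The SD describes single genes, not the error of a median, and FOXA1 and GATA3 are among the 18. Over 11 luminal genes, with transcription factors and KIT left out, the median was also -0.2 (-0.42 to 1.39). The luminal list moved down (camera adjusted p = 0.0212), with adjusted p = 0.756 with an estimated correlation. It was not called without the libraries of high muscle score. Lower RNA quality of malignant libraries was argued against by RNA integrity itself, which differed by -0.0621 between malignant and benign libraries (classes permuted within dogs, adjusted p = 0.93). The ratio with RNA integrity as a covariate was 1.08, and 1.01 against the same 81 libraries without it. With so small a class difference the covariate could hardly move the log2 changes, so that the ratio adds little. Without dog 54 PGR, PRLR, ESR1 and FOXA1 lost their calls (adjusted p = 0.202, 0.216, 0.304 and 0.216), while no omission of 1 dog brought their log2 changes above -1.38, -1.25, -1.17 and -1.37.

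The third pattern was the higher level of cartilage matrix genes in both tumor classes. Without complex adenomas and mixed carcinomas the median ratio was 0.82 over 10 called values. The lower quartile of 0.528 lay above but close to the bound of 0.5 set for histology as the whole cause, and single values went down to 0.311. The 10 values pool 4 of malignant and 6 of benign against normal libraries. The omission took 4 of 22 malignant but 18 of 41 benign libraries. The pooled median thus does not show the ratio of either class alone, and complex histology stays open as a cause in benign tumors. Muscle in normal libraries was argued against by a ratio of 0.9. RNA integrity and adipocyte content, which also differed between normal and tumor libraries, were not weighed for this pattern and stay open. In benign against normal libraries the cartilage list was not called with the adipocyte score as a covariate. The class itself stays open as an untested explanation.

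Other groupings of the same samples were run with classes shuffled within dogs, 100 per comparison with the given one included. As many genes as the 1227 of malignant against normal were called in 1 of 100 (highest other 309), and as many as the 153 of malignant against benign in 1 of 100 (highest other 18). For benign against normal 2 of 100 called as many as 2002 (highest other 3276). For the histology types 24 groupings were run, with complex adenomas and adenomas shuffled within dogs and the other types within their class across dogs, so that the pairing by dog was not held for those. As many genes as the 10 of complex adenoma against adenoma were called in 2 of 24 (highest other 254), so that these calls cannot be set apart from the other groupings. As many as the 2 of carcinoma in situ against carcinoma were called in 5 of 24 (highest other 5), so that the given labels did not stand apart. For the 3 comparisons with 0 called genes the outcome was fixed, since all 24 groupings call at least 0, and nothing follows from them (highest other 61 for mixed carcinoma against carcinoma, 682 for atypia against lobular hyperplasia and 27 for lobular hyperplasia against duct ectasia, which was higher with more groupings).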

How the results depend on the processing

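Chosen after the data were seen were the omission of libraries with a high muscle score and of single libraries from the list tests, the fits of the 81 libraries of known RNA integrity and of the 59 tumors of known diameter without the covariate, and the pairs within library preparations and across sequencing runs. The cause of the moves below was not tested except where the alternative's construction gives it (fewer libraries, a minimum fold) or where the same libraries were fitted without the covariate. Genes in malignant against normal libraries numbered 103 with RNA integrity as a covariate (1518 in the same 81 libraries without it), 20 with the adipocyte score as a covariate, 2151 with DESeq2, 4 against a 1.5-fold change, 759 without atypias and carcinomas in situ and 0 without the muscle libraries, against 1227. Benign against normal gave 788 with sequencing run, 27 with RNA integrity (2588 in the same 81 libraries without it), 0 with the adipocyte score, 39 against a 1.5-fold change, 987 without complex adenomas and mixed carcinomas and 2 without the muscle libraries, against 2002. Malignant against benign gave 362 with no dog block, 304 with dog as a random effect, 0 with summed counts, 0 with sequencing run, 554 with DESeq2, 0 against a 1.5-fold change, 27 without atypias and carcinomas in situ, 0 without complex adenomas and mixed carcinomas, 2 in the 59 tumors of known diameter with that as a covariate, 2 in the same tumors without it and 15 without the muscle libraries, against 153. Complex adenoma against adenoma gave 176 with no dog block, 51 with dog as a random effect, 0 with summed counts, 0 with sequencing run, 20 with RNA integrity, 19 in the same 81 libraries without it, 22 with the adipocyte score, 2 with no filter, 200 with DESeq2, 0 against a 1.5-fold change, 0 without the muscle libraries and 0 with benign samples only, against 10. Carcinoma in situ against carcinoma gave 14 with no dog block, 4 with dog as a random effect, 0 with summed counts, 0 with sequencing run, 10 with RNA integrity, 17 in the same 81 libraries without it, 237 with DESeq2, 0 against a 1.5-fold change and 0 without the muscle libraries, against 2. Mixed carcinoma against carcinoma gave 13 with no dog block, 4 with dog as a random effect and 92 with DESeq2, atypia against lobular hyperplasia 49, 1 and 108 in the same order, lobular hyperplasia against duct ectasia 62 with no dog block and 122 with DESeq2, and diameter 12 with no dog block and 49 with DESeq2, each against 0.

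The pairing by dog, left out in the fits with no replicate block, gave 1266 genes for malignant against normal and 1427 for benign against normal (707 upward, 720 downward), and changed the other counts as above. With the block 86 gene lists were called and without it also 86, not all of them the same lists. Endothelium in malignant against normal and immediate early genes in both comparisons with normal were not called without it. Of 234 list tests 86 were called, 0 with an estimated correlation and 7 with fry. Those 7 were the adipocyte and milk lists in both comparisons with normal, and the cartilage list in malignant against normal. Hormone response in malignant against normal and against benign made up the rest. Fry called 0 lists in the comparisons of histology types and in diameter. Called lists numbered 87 with RNA integrity, 95 in the same 81 libraries without it, 75 with the adipocyte score and 78 without the muscle libraries. In the order malignant against normal, benign against normal, malignant against benign, complex adenoma, mixed carcinoma, carcinoma in situ, atypia, lobular hyperplasia and diameter, the lists called were 11, 11, 7, 9, 9, 13, 4, 6 and 16. Kept in the same direction were 8, 4, 7, 9, 2, 10, 1, 5 and 14 with the adipocyte score and 9, 9, 6, 9, 6, 11, 3, 2 and 16 with RNA integrity. Where the adipocyte list was among those called, its loss with its own score follows from construction. In the same 81 libraries without RNA integrity 11, 10, 7, 9, 5, 11, 3, 4 and 16 were kept, without the muscle libraries 10, 8, 5, 9, 7, 12, 2, 3 and 13, and with no dog block 9, 10, 6, 5, 4, 9, 3, 4 and 10. Endothelium in malignant against normal and immediate early genes in benign against normal turned upward with the adipocyte score. Leaving out single mixed carcinoma, carcinoma in situ or atypia libraries gave 80 (malignant replicate 3) to 92 (normal replicate 16) list calls. RLE size factors shifted the median log2 change by at most 0.015 in size.

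Leaving out 1 dog gave 288 (dog 13) to 1429 (dog 18) genes for malignant against normal and 624 without dog 89, and 977 (dog 13) to 3117 (dog 47) for benign against normal and 1260 without dog 83. For malignant against benign it gave 2 (dog 54) to 293 (dog 70), with 47 without dog 1, 23 without dog 13, 39 without dog 29, 90 without dog 36, 94 without dog 47 and 33 without dog 82. For complex adenoma against adenoma it gave 0 (dogs 34, 69 and 82) to 43 (dog 18), with 3 without dog 1, 5 without dog 13, 1 without dog 17, 26 without dog 29, 3 without dog 36, 4 without dog 54, 2 without dog 70, 16 without dog 83 and 1 without dog 89. Leaving out single libraries gave 0 (malignant replicate 3) to 12 (malignant replicate 20) for carcinoma in situ and 1 without malignant replicate 12, 0 to 2 (malignant replicate 4) for mixed carcinoma and 0 to 0 for atypia. Leaving out 1 dog gave 0 to 0 for lobular hyperplasia against duct ectasia and 0 to 1 (dog 34) for diameter.

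Of the named genes called in the class comparisons and in complex adenoma, 24 of 46 in malignant against normal, 19 of 56 in benign against normal, 25 of 26 in malignant against benign and 7 of 7 in complex adenoma lost the call without at least 1 dog. Over the alternatives, 233 of 699 values of named genes lost the call and 5 gained it in malignant against normal, 326 of 868 and 4 in benign against normal, 229 of 464 and 0 in malignant against benign, 45 of 91 and 0 in complex adenoma, and 12 of 30 and 0 in carcinoma in situ. The others kept direction and side of the threshold, apart from the reversals that follow. In malignant against normal CFD, itself a member of the adipocyte list, turned to 0.07 and EGFL7 to 0.1 with the adipocyte score. In benign against normal CKM turned to 0.23 with the adipocyte score, and the uncalled genes near 0 turned sign as follows: ESR1 was -0.02 with sequencing run, PGR 0 with no dog block, -0.05 with dog as a random effect, -0.04 with sequencing run and -0.03 without complex adenomas and mixed carcinomas, ERBB2 0.03 with RNA integrity, and KRT5 0.24 with sequencing run, 0.05 with RNA integrity, 0.06 in the same 81 libraries without it, 0 with RLE size factors, 0.02 with no filter, 0 with DESeq2, 0.03 without atypias and carcinomas in situ and 0.02 without complex adenomas and mixed carcinomas. The remaining values kept direction: the correlation over split dogs was 0.416 for genes with an average log2 CPM of at least 3 and 0.357 by Spearman, and the difference in similarity within dogs was 0.0258 over all genes, 0.113 by Spearman, 0.144 within library preparations and 0.102 across sequencing runs. The series-wide table in place of the counts was not run, since it holds scores.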

Other observations

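Further members of the lists changed beside those named above. In malignant against normal libraries the desaturases FADS2 (0.86 ± 0.17) and FADS1 (0.82 ± 0.24), which make polyunsaturated fatty acids, rose and AGPAT2 (-0.58 ± 0.16) fell, while the fatty acid synthesis list as a set was not called. Among Wnt targets SFRP1 (1.05 ± 0.32) rose and the growth factor gene BMP4 (-1.41 ± 0.33) fell, and BMP4 (-1.16 ± 0.28) and NKD2 (-1.41 ± 0.38) fell in benign against normal libraries. The cadherin gene CDH2 rose by 1.76 ± 0.55 and the integrin gene ITGA6 by 1.07 ± 0.27 in malignant against normal libraries. The epithelial genes MUC1 (-1.51 ± 0.44) and ELF5 (-1.84 ± 0.31) fell in benign against normal libraries, and OXTR, the oxytocin receptor gene, rose (0.95 ± 0.32). ANGPTL4, a regulator of lipid uptake, fell by 1.35 ± 0.29 in benign against normal libraries while EGLN3 (0.89 ± 0.29) and VEGFA (0.74 ± 0.26) of the same hypoxia list rose.

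RNA integrity moved with tissue scores inside dogs when the classes, which differed in both, were pooled. Over 81 libraries its correlation with the adipocyte score within dogs was -0.581 (rank correlation -0.544; adjusted p = 7.5e-05 over 15 relations), with the skeletal muscle score -0.405 (rank correlation -0.335; adjusted p = 0.017; -0.277 without the 2 most extreme libraries) and with the proliferation score 0.499 (rank correlation 0.471; adjusted p = 0.00034). Inside single classes the correlation passed for 1 of the classes per score, and the rank correlation passed for the proliferation score in normal libraries alone. For the adipocyte score they were -0.383 in normal (adjusted p = 0.096), -0.398 in benign (0.024) and -0.395 in malignant libraries (0.12). For the muscle score they were -0.465 (adjusted p = 0.048), -0.178 (0.28) and -0.0251 (0.93), and for the proliferation score 0.493 (adjusted p = 0.037), 0.323 (0.057) and 0.483 (0.054), in the same order. Rank correlations were -0.454 (adjusted p = 0.074), -0.223 (0.19) and -0.385 (0.14) for the adipocyte score, -0.435 (adjusted p = 0.079), -0.0284 (0.86) and -0.0926 (0.76) for the muscle score and 0.566 (adjusted p = 0.02), 0.255 (0.14) and 0.46 (0.079) for the proliferation score.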
